A study of Bacillus subtilis with 6 samples.

How the data were processed

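RNA of B. subtilis KS002 (a PY79 derivative) with and without targocil was measured on 6 2-colour spotted arrays, 1 array and 1 dye swap for each of 3 biological replicates with independent RNA preparations, per the labels. On the unswapped arrays untreated RNA carried Alexa Fluor 555 (532 nm) and targocil RNA Alexa Fluor 647 (635 nm, the red channel), per the labels. For the dye swaps the labels give the same dyes to the same RNA, while the series description calls them dye swaps. The log2 ratios of array and swap before any turning correlated at -0.80, -0.15 and -0.60 across genes in replicates 1, 2 and 3, so the swaps were turned as the description states. After turning, the unswapped array of replicate 2 correlated at 0.15 with its own swap (0.48 among genes above the median intensity). That is below its 0.25 to 0.59 with the arrays of other replicates, so replicate 2 reproduced poorly between its arrays. The unturned reading is among the alternatives.

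The deposited tables hold intensities per spot, as foreground and local background medians at both wavelengths, per the file headers. Each table lists 8448 spots, with 4116 gene probes at 2 spots per gene, 192 blank spots and 24 random-sequence control spots. The values show that the authors had rescaled these intensities: 5.49% to 40.7% of whole numbers are absent from the 532 nm columns against 0% at 635 nm, 9 and 4 spots of 2 arrays exceed the scanner limit of 65535 at 532 nm, and 635 nm ends in a plateau at 54813 and 60765 on the replicate 1 arrays (7 and 6 spots). The authors also deposited the background-subtracted intensities and their ratio of 635 nm over 532 nm, and that ratio was used here as deposited. The authors' value table holds log2 of that ratio without turning or centring; every value below 0 is blank in it, and its column medians, from 0.95 to 2.22, are therefore medians of positive values only. The scanner, its software, the array's genome build and its annotation are not given in the sources used here. An unnamed column of 0 and 1 in 3 tables was not used here.

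Intensities were corrected with limma 3.58.1 in R 4.3.3 (normexp, offset 50, fitted on all spots) and log2 ratios were normalized within each array by global loess with control spots at weight 0. The 2 spots of a gene were averaged, dye swaps were turned, and array and swap of a replicate were averaged. The mean of the 3 replicate ratios was tested against 0 with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over 4116 genes and a threshold of 0.05. Within-array normalization removes any change common to all genes. The replicates are separate RNA preparations, and treated and untreated RNA of a replicate share a culture and an array. Array and swap of a replicate deviated together from the mean of their kind with correlations of 0.78, 0.41 and 0.03. They were treated as 1 replicate because the series description states that they hold the same RNA.

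A gene counted as above the control spots where the mean of its background-subtracted spots exceeded the 95th percentile of blank and random-sequence spots in that channel. Median background-subtracted intensities per array ran from 42 to 209 at 635 nm and from -6 to 117 at 532 nm, and 13.8% to 69.0% of genes lay above the controls per channel. A gene above the controls on no array of a condition has only a bound there. The fold printed for it sets the mean of the brighter condition against the higher of the probe's own level and the lowest level above the controls, per channel after loess and Aquantile scaling. It bounds the mean over replicates and is not a confidence limit, so a single replicate can lie below it.

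Before the data were examined, 41 gene lists were fixed from general knowledge of B. subtilis, and camera (preset correlation 0.01) was run on those with at least 5 measured members, with an estimated correlation and fry as alternatives. Counts adjusted over the list alone use Benjamini-Hochberg within a list, without adjustment over the 41 lists. This looser count was not among the tests fixed beforehand. Members of a list can move together, so such counts are not independent calls. The genes to name were fixed as the 12 rising and 12 falling genes with the largest changes among those past the threshold with the same sign in 3 replicates, up to 4 members with the smallest adjusted p of each called list and of the SigM, SigW, SigX, LiaRS, WalR, wall teichoic acid and peptidoglycan lists, and tagG and tagH. The genes fabF and qoxD, and all single genes of the closing observations, were chosen after their values were seen. Gene names are the file's. Of these, 3036 are symbols in the RefSeq table of assembly ASM904v1 and 1080 are kept as older names; that table was used only for names and neighbours.

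The fit was tested on simulated data for the comparison of targocil against untreated, with 4116 genes. It recovered 100% of genes set to a log2 ratio of -2, 56% at -1, 68% at 1 and 98% at 2, with 5 wrong calls among 178. Camera called the list set to rise and 0 other lists. The genes set to these ratios were drawn from the brighter genes, and the replicates were given equal spread, so recovery in the real data may be lower. Noise was drawn independently for each gene, so the simulation does not test camera's preset correlation. In the real data the estimated correlation was 0.72 for the SigM list and 0.98 for the Spx list.

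The alternatives were other background corrections, median centring, scaling between arrays, a filter on dim genes, fits of the 6 arrays with a replicate block, with and without a dye term (statmod 1.5.0), each dye orientation alone, swaps not turned, eBayes with trend and robust, each replicate left out, and an unmoderated one-sample test. The deposited ratios, a filter on genes above the controls and 2 fits that leave out a single dye-swap array were added after the data were seen.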

Results

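The transcriptome of Bacillus subtilis strain KS002 was compared with and without targocil, a small molecule that inhibits TarG, a subunit of the Staphylococcus aureus exporter of wall teichoic acid. Wall teichoic acids are anionic polymers joined to the peptidoglycan of the cell wall. KS002 lacks its own tagG and tagH and exports the polymer through the S. aureus TarGH proteins, made under an inducible promoter, so the comparison asks which genes respond when that exporter is inhibited. Cultures grown to an OD600 of 0.4 were divided, and 20 µM targocil or the solvent was given for 30 minutes. RNA from 3 independent experiments was hybridised to 2-colour spotted arrays, each experiment on 1 array and on 1 dye-swapped array with the same RNA, which gave 6 arrays and n = 3. Each array carried 4116 gene probes with 2 spots per gene. Between 569 and 2839 of the 4116 genes lay above the control spots in a given channel of a given array, and 446 did so in both conditions on every array. The number of arrays limits the precision, and the median standard error of a gene's log2 ratio was 0.168. All ratios below are log2 of targocil over untreated, so a negative value means lower with targocil.

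The deleted genes came first. The tagG probe had background-subtracted intensities from 57.5 to 330 over the 12 channels and lay above the control spots in 9 of them, and the tagH probe had intensities from 130 to 775.5 and lay above them in 10. They lay between the 39.0 and 84.3 percentiles of gene probes for tagG and between 59.7 and 83.5 for tagH. Of the 5 failures 4 were in the red channel of replicate 3, where random-sequence control spots carried signal. Their log2 ratios were -0.01 ± 0.23 for tagG and -0.06 ± 0.17 for tagH (SD, n = 3), with adjusted p = 0.982 and 0.828. The position of these probes relative to the deletion is not given in the sources used here, so their signal does not check the strain.

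With targocil, the 6 adjacent genes yceC to yceH, 3 of 37 genes of the SigM regulon and 3 of 14 of the CtsR and HrcA regulons rose, and all 9 genes of ATP synthase, 7 of 17 of fatty acid synthesis and 23 of 51 for ribosomal proteins fell. As lists, 0 were called with an estimated correlation (smallest adjusted p = 0.689). That setting rests on 2 residual degrees of freedom and could call little. Among 4116 genes tested with limma, 157 passed an adjusted p of 0.05, of which 47 rose and 110 fell. At least 2-fold changes were found for 134 of the 157 (40 rose and 94 fell). The 47 include the yomS probe of the SPβ prophage, which PY79 is known to lack. Among genes past the threshold those that rose most were ypbG, at 2.44 ± 0.92 or 5.41-fold (SD, n = 3, adjusted p = 0.0405), and clpE, an ATPase subunit of the Clp protease, at 2.42 ± 1.01 (adjusted p = 0.0449). They were followed by yceE at 2.25, ywaC at 2.24, yceC at 2.23, yceD at 2.22, yjfC at 2.06, yqjL and ypbH at 1.99 each, and xkdT, yqjM and yfiH at 1.85 each. The gene past the threshold that fell most was ptsG, the glucose transporter of the phosphotransferase system, at -3.76 ± 1.30 or 13.5-fold lower (adjusted p = 0.0343). It was followed by 7 genes of ATP synthase between atpB at -3.13 and atpG at -2.55, by fabG at -2.61 and fabD at -2.53 of fatty acid synthesis, by treA, the phosphotrehalase, at -2.45, and by odhA, a subunit of 2-oxoglutarate dehydrogenase, at -2.41. All 157 genes had the same sign in 3 replicates, as did 51.5% of all genes against 25% by chance.

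The smallest adjusted p was 0.0286, and 1071 genes had an unadjusted p under 0.05, so the number past the threshold moved with single choices. It was 503 without replicate 1, 0 without replicate 2 (949 at an unadjusted p under 0.05), 0 without replicate 3 (500 unadjusted), 0 without background correction and 745 when both arrays of each replicate were kept with the replicate as a block, called the blocked fit below; 29.9% of the calls rose, against 45.0% with median centring and 44.0% with arrays scaled to one spread. All 157 genes were among the 503 and among the 745. The blocked fit counts array and swap of the same RNA in part as separate (consensus correlation 0.118). Its p-values are likely too small, so a gene said below to pass in it is not a call at n = 3. Among genes named in the report as changed, some probes lay above the control spots on few of the 6 arrays of a condition: with targocil pbuX and yfiZ on 1, feuA on 2, and fabD, resA and yclQ on 3, and untreated yjfC and uvrA on 3. Among named genes that did not pass, with targocil yjeA, ydjM, tlpA, pyrR and yuaB did so on 1 array, and untreated yflT and ybgB on 2.

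**Figure D1:**
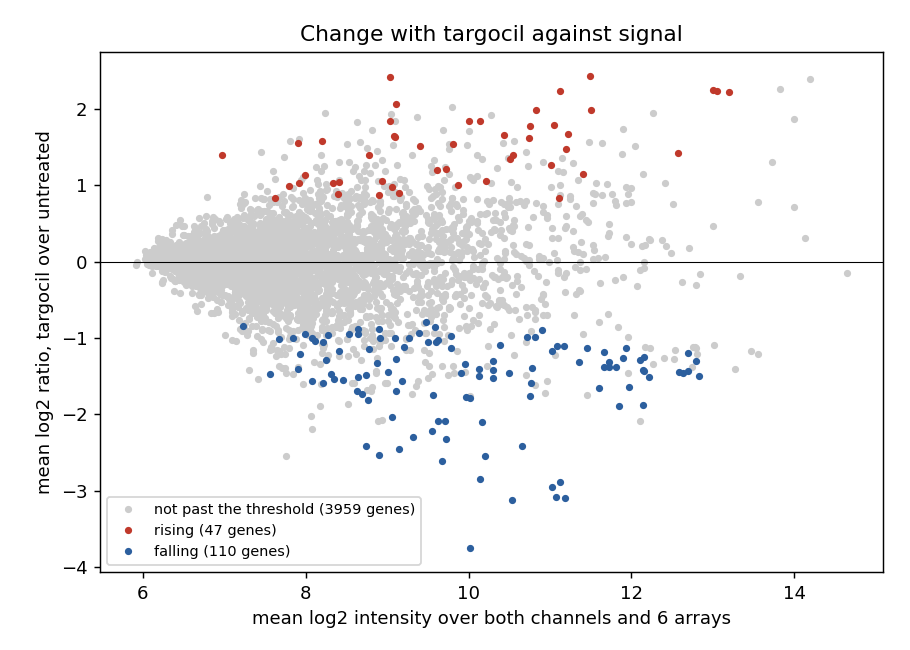
Each point is a gene, with its mean log2 intensity over both channels and 6 arrays on the horizontal axis and its mean log2 ratio of targocil over untreated (n = 3) on the vertical axis. Red points are the 47 genes that rose, blue points the 110 that fell, and grey points the other genes; ptsG lies lowest at -3.76.

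**Figure D2:**
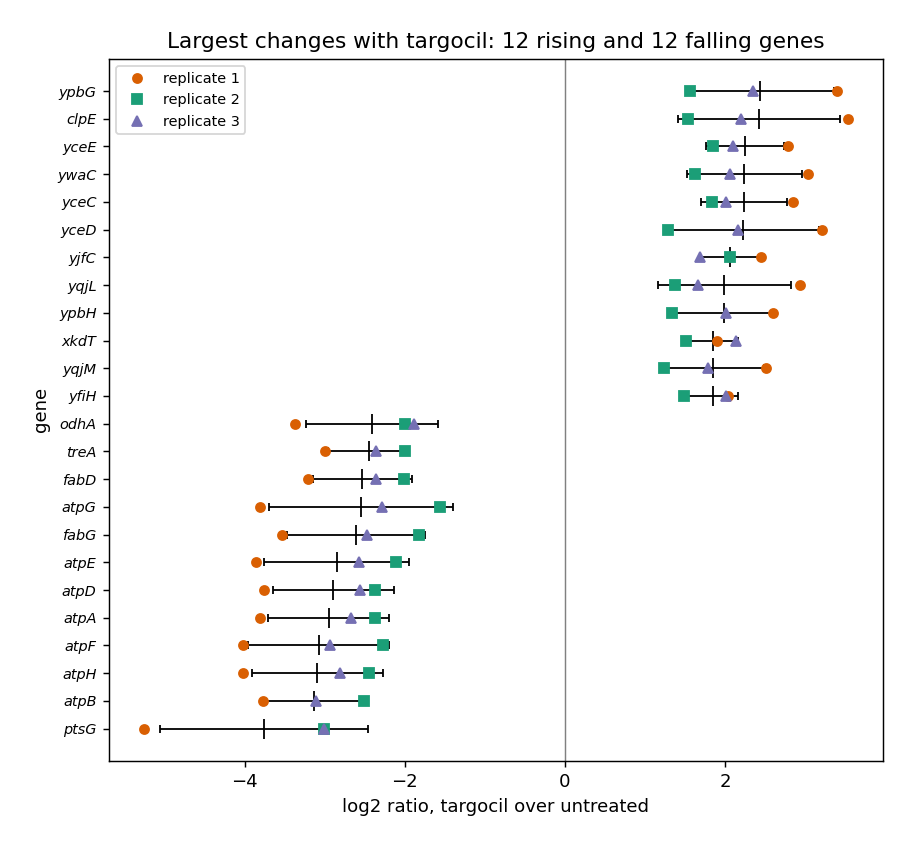
The 12 genes that rose most and the 12 that fell most among those past the threshold with the same sign in 3 replicates. The log2 ratio of targocil over untreated is on the horizontal axis. Coloured symbols are the 3 replicates (each the mean of an array and its dye swap), the vertical tick is their mean and the bar is 1 SD; replicate 1 lies farthest from 0 for most of them.

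The SigM list held rising genes, and the rising genes of the SigW list all lay in its adjacent set yceC to yceH. The SigM regulon, controlled by an extracytoplasmic function sigma factor that answers to impaired cell wall synthesis, had 37 measured members, of which 3 rose and 0 fell: ypbG, ywaC, a synthetase of the alarmone ppGpp, at 2.24 ± 0.72, and yqjL at 1.99 ± 0.83. Another member, yjbC, had 2.39 ± 1.12 and missed the threshold (adjusted p = 0.0511; 0.00136 in the blocked fit). Adjusted over the list alone, 22 SigM members rose, and 25 passed in the blocked fit. The list median was 1.01, with replicate medians of 2.02, 0.48 and 0.78, and it was 0.63 without replicate 1. The camera test called the list higher (adjusted p = 8.92e-11), and adjusted p = 0.689 with an estimated correlation. The SigW regulon, named for a second envelope stress sigma factor, held 54 measured genes. All 6 genes of its adjacent set yceC to yceH rose, by log2 ratios from 1.26 to 2.25, with yceH at 1.48 ± 0.39 (adjusted p = 0.0343). The fatty acid synthesis genes fabHA, at -2.04 ± 0.67, and fabF, at -1.74 ± 0.70, fell, and the other 46 members did not pass. For SigW genes adjusted over the list alone, 6 rose and 3 fell, and the blocked fit gave 6 and 8. As a list it was not called (median -0.49, camera adjusted p = 0.0609). It was called lower in 4 of 17 alternatives with the preset correlation and swaps turned, without replicate 2 (adjusted p = 0.00398), without replicate 3 (adjusted p = 4.39e-04), in the dye-swap arrays alone (adjusted p = 0.0178) and with the trend and robust fit (adjusted p = 0.00363). Without replicate 1 the SigW median was 0.01 (adjusted p = 0.383), and adjusted p = 0.910 with an estimated correlation. Its replicate medians were -1.49, 0.10 and -0.01.

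The joint list of the SigV and SigY regulons had 10 measured members, of which 0 passed over all genes and 8 rose when adjusted over the list alone. Its members sigV, ybgB, yxlF and sigY had log2 ratios of 1.18 ± 0.76, 1.02 ± 0.49, 0.96 ± 0.43 and 0.84 ± 0.31, with adjusted p from 0.0649 to 0.0960, and all 4 passed in the blocked fit (adjusted p from 0.00562 to 0.00815); without replicate 1 sigV had 0.77. The list was called higher (median 0.80, camera adjusted p = 1.44e-04), with adjusted p = 0.689 with an estimated correlation. Of the 12 measured genes of the SigX regulon 0 passed, also adjusted over the list alone, and the list was not called (adjusted p = 0.268), although it was called higher with the authors' deposited ratios (adjusted p = 0.0195). Its dltA, dltC, dltD and dltE, of the operon that adds D-alanine to teichoic acids, had 0.98 ± 0.64, 0.88 ± 0.62, 0.96 ± 0.79 and 0.74 ± 0.81. In the blocked fit dltA, dltC and dltD passed (adjusted p = 0.0212, 0.0359 and 0.0398), and without replicate 1 the 4 had 0.61, 0.53, 0.51 and 0.34 (dltE 1.15 without replicate 2). The LiaRS regulon, which many inhibitors of the lipid II cycle induce, had 0 of 9 members past the threshold, also adjusted over the list alone. Its yvqI and yvqH, the file's names for liaI and liaH, had 0.59 ± 0.18 and 0.55 ± 0.23 (adjusted p = 0.0953 and 0.112; 0.0286 for yvqI in the blocked fit). In the dye-swap arrays alone yvqH had 0.11, and in the unswapped arrays alone 0.999. Of the same list yvqF had -0.25 and yvqC -0.29. Without replicate 1 yvqF and yvqC had -0.07 and -0.04, yvqF had -0.42 without replicate 2 and yvqC -0.50 without replicate 3. The list median was -0.07, the mean 0.03 and the camera direction upward (adjusted p = 0.854), so these differed in sign; the median was 0.04 without replicate 1 and 0.09 in the dye-swap arrays alone. Of 8 measured genes of the WalR regulon of wall turnover 0 passed, also adjusted over the list alone (camera adjusted p = 0.592). The 4 with the smallest adjusted p were yvcE at -0.70 ± 0.51 (0.0390 in the blocked fit), ydjM at -0.54, sigI at 0.26 and yjeA at -0.44. Without replicate 1 sigI and yjeA had 0.09 and -0.04, yjeA had -0.87 without replicate 2 and 0.17 in the unswapped arrays alone, and without replicate 3 yvcE and ydjM had -0.405 and -0.28.

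The list of wall teichoic acid synthesis includes tagG and tagH, which KS002 lacks (log2 ratios -0.01 and -0.06). Of its 17 measured genes 0 passed, also adjusted over the list alone. The list was not called (median -0.03, camera adjusted p = 0.594), and its median was -0.09 without replicate 2 or without replicate 3. The nearest were tagB at -0.85 ± 0.42 and tagO at -0.52 ± 0.21, with adjusted p = 0.0820 and 0.119 (0.0107 and 0.0430 in the blocked fit), and yhxB and tagD had 0.73 ± 0.80 and -0.43 ± 0.47 (0.29 and -0.17 without replicate 1). Of 33 measured genes of peptidoglycan synthesis 4 fell and 0 rose. These were spoVE at -1.27 ± 0.36, dacA, a carboxypeptidase that trims peptidoglycan, at -1.12 ± 0.37, murD, a ligase of the cytoplasmic precursor, at -1.06 ± 0.30, and mraY, which makes lipid I, at -0.88 ± 0.19. Among peptidoglycan genes 5 rose and 7 fell when adjusted over the list alone, the blocked fit gave 7 and 9, and the list was not called (median 0.10, adjusted p = 0.858), although it was called higher with the deposited ratios (adjusted p = 0.0153). The peptidoglycan median turned to -0.02 without replicate 1, and was 0.21 without replicate 2 and 0.28 without replicate 3. In the dye-swap arrays alone spoVE, murD and mraY had -0.72, -0.69 and -0.57. The peptidoglycan list shares murB, murF, murG, mreB, ponA and further members with the SigM list, so the counts and medians of these lists are not independent.

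Of 14 measured members of the CtsR and HrcA heat shock regulons 3 rose, clpE, mcsB, an arginine kinase that marks proteins for degradation, at 1.61 ± 0.63, and its activator mcsA at 1.39 ± 0.45, while hrcA had 1.34 ± 0.58 (adjusted p = 0.0533; 0.00231 in the blocked fit). A total of 11 rose when adjusted over the list alone, as in the blocked fit. The list median was 1.35, and 0.86 without replicate 1. Of the 5 genes of the CssRS and htpG list 2 rose, the membrane proteases htrA at 1.78 ± 0.39 and yvtA (htrB) at 1.67 ± 0.18, both with adjusted p = 0.0286, and 3 rose when adjusted over the list alone; cssS and htpG had 0.41 and 0.40 (htpG 0.19 in the dye-swap arrays alone). Its list median of 0.54 was 0.84 without replicate 1. Of the 8 genes of the list linked to Spx, a regulator of thiol stress, 0 passed over all genes and 8 rose when adjusted over the list alone or in the blocked fit. Its trxA, the thioredoxin gene, had 1.58 ± 0.68, yppQ 1.33 ± 0.55, nfrA 1.71 ± 0.77 and yugJ 1.93 ± 0.91, with adjusted p from 0.0511 to 0.0533 (0.00153 to 0.00369 in the blocked fit). All these lists were called higher by camera, with adjusted p = 4.15e-06 for CtsR and HrcA, 5.33e-04 for CssRS and htpG and 2.34e-06 for Spx, and each had adjusted p = 0.689 with an estimated correlation. The CssRS and htpG list was also called by fry (adjusted p = 0.00758), which tests whether the members move one way.

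The wider stress lists of SigB and the SOS response had smaller medians. In the SigB general stress regulon 2 of 67 measured genes rose, gspA at 1.40 ± 0.56 and yvyD, a ribosome hibernation factor, at 0.83 ± 0.11, 0 rose when adjusted over the list alone, and 14 passed in the blocked fit. Its yvgN had 1.22 ± 0.61 (adjusted p = 0.0664; 0.00670 in the blocked fit) and yflT 0.84 ± 0.25 (0.44 in the dye-swap arrays alone). The list median was 0.38, the camera test called it higher (adjusted p = 8.92e-11), and adjusted p = 0.689 with an estimated correlation. In the SOS response to DNA damage 1 of 14 genes rose, uvrA of nucleotide excision repair at 1.04 ± 0.28, and 2 rose when adjusted over the list alone (3 in the blocked fit). Its uvrB, lexA and ynzC had 0.74 ± 0.28, 0.65 ± 0.46 and 0.68 ± 0.58, and uvrB and lexA passed in the blocked fit (adjusted p = 0.0426 and 0.0483). Without replicate 1 lexA and ynzC had 0.40 and 0.36. The list was called higher (median 0.36, adjusted p = 0.00849) but not without replicate 1 (adjusted p = 0.0745) or with plain background subtraction (adjusted p = 0.0642), and adjusted p = 0.730 with an estimated correlation.

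All 9 genes of ATP synthase fell, also adjusted over the list alone, led by atpB at -3.13 ± 0.63, atpH at -3.09 ± 0.82, atpF at -3.08 ± 0.88 and atpA at -2.95 ± 0.76, with atpD at -2.89 and atpE at -2.85 behind them. The list median was -2.89, with replicate medians of -3.80, -2.28 and -2.64. Of 28 respiration genes 5 fell and 0 rose. These were qoxC and qoxD of the aa3 quinol oxidase at -2.22 ± 0.49 and -1.48 ± 0.49, sdhB of succinate dehydrogenase at -1.59 ± 0.34, resA at -1.28 ± 0.29 and cydB of the bd oxidase at -1.15 ± 0.20. Adjusted over the list alone, 22 respiration genes fell and 2 rose, and the blocked fit gave 20 and 2. Of 13 genes of the TCA cycle 2 fell, odhA and sdhB, and 8 fell when adjusted over the list alone, as in the blocked fit; sdhA and sdhC had -1.49 ± 0.69 and -1.37 ± 0.61 (adjusted p = 0.0533 for both; 0.00296 and 0.00320 in the blocked fit). The TCA list median of -1.36 was -0.81 without replicate 1, and with the authors' deposited ratios the list was not called (adjusted p = 0.115). Of 17 genes of fatty acid synthesis 7 fell, among them fabG at -2.61 ± 0.86, fabD at -2.53 ± 0.62, plsX, which starts phospholipid synthesis, at -2.29 ± 0.76, and acpA, the acyl carrier protein gene, at -1.41 ± 0.31. A total of 12 fell when adjusted over the list alone, as in the blocked fit, and the median of -1.41 was -0.89 without replicate 1. Camera called all of these lists lower, with adjusted p = 8.38e-10 for ATP synthase, 2.61e-10 for respiration, 3.40e-05 for the TCA cycle and 2.24e-08 for fatty acid synthesis, and each had adjusted p = 0.689 with an estimated correlation.

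Of 51 measured genes for ribosomal proteins 23 fell and 0 rose, 45 fell when adjusted over the list alone, and 42 fell in the blocked fit. Examples were rplJ and rplL of the ribosomal stalk at -1.66 ± 0.43 and -1.53 ± 0.32, rplX at -1.39 ± 0.19 and rpmD at -1.38 ± 0.10. The list median was -1.16, and 46 of 51 genes were lower in all 3 replicates. Of 19 genes of purine synthesis and uptake 1 fell, pbuX, a xanthine permease, at -1.48 ± 0.28, and 13 fell when adjusted over the list alone, as in the blocked fit. The other members named were xpt at -0.83 ± 0.23, guaA at -1.03 ± 0.44 and pbuG. The pbuG probe lay above the control spots on 0 of 6 targocil arrays, with a mean bound of 1.52-fold lower with targocil. It did not pass (adjusted p = 0.0828), and its replicate 2 had -0.46. In the blocked fit xpt, guaA and pbuG passed (adjusted p = 0.00499, 0.00415 and 0.00499). Both lists were called lower (adjusted p = 1.76e-22 and 4.42e-07) and each had adjusted p = 0.689 with an estimated correlation. Of 10 genes of pyrimidine synthesis 0 passed, also adjusted over the list alone, and pyrR, pyrC, pyrK and pyrD had -1.05 ± 0.83, -0.71 ± 0.70, -0.57 ± 0.40 and -0.32 ± 0.24, with pyrR and pyrK past the threshold in the blocked fit (adjusted p = 0.0217 and 0.0490). Without replicate 1 these 4 had -0.57, -0.32, -0.35 and -0.19. The pyrimidine list was called lower (adjusted p = 0.0417) but not in 12 of 17 alternatives, among them without replicate 1 (adjusted p = 0.851), the unswapped arrays alone (adjusted p = 0.329) and median centring (adjusted p = 0.0503), and adjusted p = 0.910 with an estimated correlation.

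Of 38 genes of the Fur iron regulon 7 fell, among them feuA, which binds iron-loaded siderophore, at -1.81 ± 0.22, yclQ at -1.47 ± 0.53, yfiZ, 2.00-fold lower, and fhuC at -0.94 ± 0.17. Adjusted over the list alone 21 fell and 1 rose, and the blocked fit gave 20 and 1. The Fur list was called lower (median -0.78, adjusted p = 4.90e-11), and adjusted p = 0.689 with an estimated correlation. On dim probes the values depended on background correction, and yfiZ had -2.53 with plain subtraction. Of 46 motility and chemotaxis genes 0 passed, also adjusted over the list alone, and 8 fell in the blocked fit. Its flhB, cheA, flgC and tlpA had -1.86 ± 1.32, -1.56 ± 1.11, -1.44 ± 1.05 and -0.53 ± 0.26, and all 4 passed in the blocked fit (adjusted p from 0.0102 to 0.0420). Without replicate 1 flhB, cheA and flgC had -1.10, -0.92 and -0.84. The replicate medians of this list were -1.56, -0.01 and -0.21, it was called lower (adjusted p = 1.04e-05) but not without replicate 1 (median -0.15, adjusted p = 0.173), and adjusted p = 0.910 with an estimated correlation. Of 20 biofilm matrix genes 0 passed, also adjusted over the list alone. The list's yuaB had -0.60 ± 0.32 (adjusted p = 0.0341 in the blocked fit) and yveN -0.51 (-0.08 in the unswapped arrays alone). Its yveP probe lay above the control spots on 0 arrays of either condition. The yvfA probe did so on 0 targocil arrays and 1 untreated array, so its bound of 1.03-fold shows no fall (adjusted p = 0.156). That list was called lower (adjusted p = 0.00818) but not in 5 of 16 alternatives, among them without replicate 1 (adjusted p = 0.593), in the blocked fit (adjusted p = 0.0953) and in the dye-swap arrays alone (adjusted p = 0.0789), and adjusted p = 0.910 with an estimated correlation. In the list of genes for glycerol, ribose, inositol and gluconate use 1 of 19 rose, glpD, glycerol-3-phosphate dehydrogenase, 2.30-fold higher (SD of log2 0.22), and 1 fell, glpF, the glycerol facilitator, at -1.56 ± 0.49 (-0.97 in the dye-swap arrays alone). Adjusted over the list alone 1 rose and 9 fell, as in the blocked fit. Its gntP had -0.93 ± 0.33 (-0.46 in the dye-swap arrays alone, adjusted p = 0.0552, and 0.0225 in the blocked fit). The rbsR probe lay above the control spots on 0 of 6 targocil arrays, with a mean bound of 2.69-fold lower. It missed the threshold (adjusted p = 0.0533, and 0.00235 in the blocked fit), and its replicate 2 had -0.76. The list was called lower (median -0.46, adjusted p = 2.23e-04), and adjusted p = 0.689 with an estimated correlation.

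**Figure D3:**
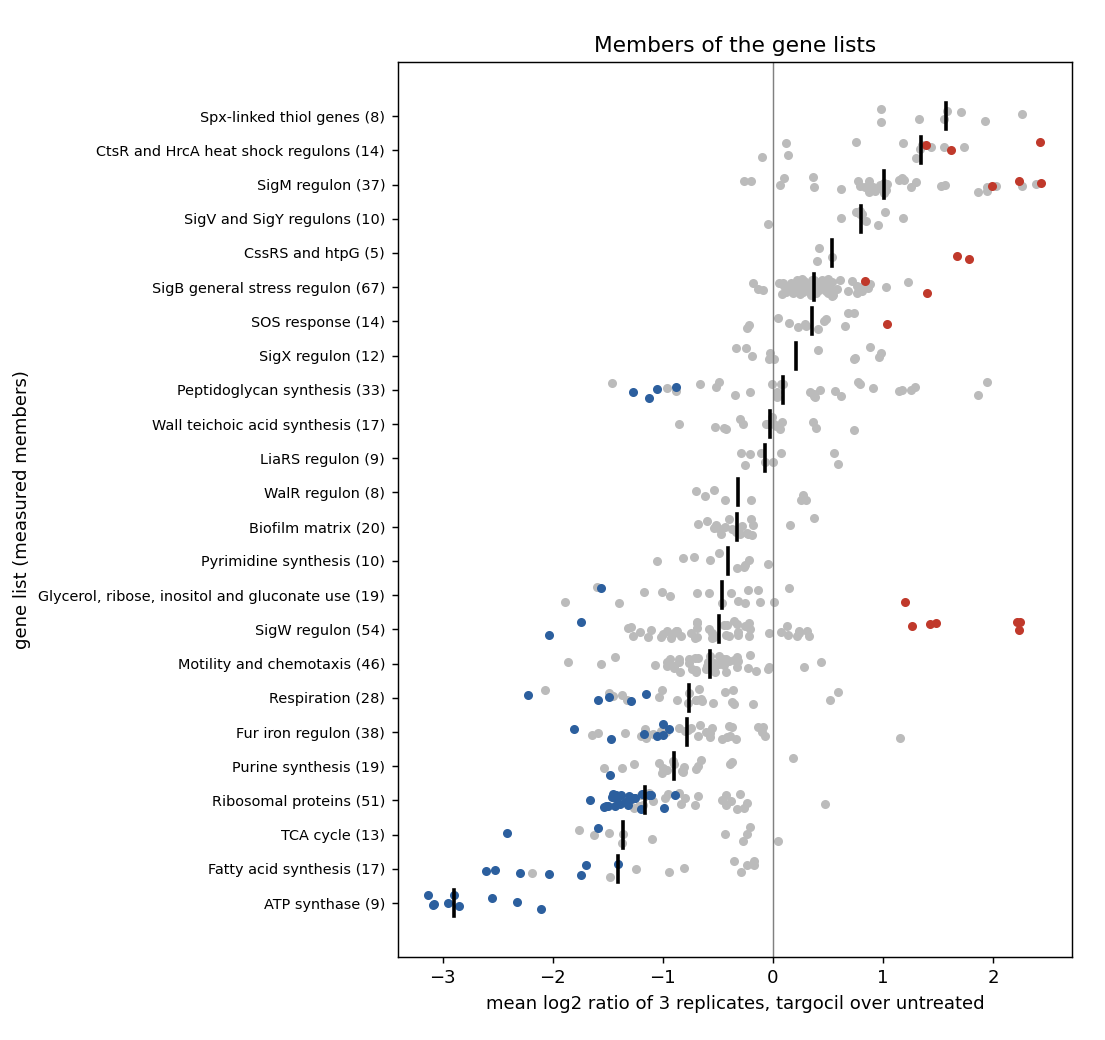
Mean log2 ratio of targocil over untreated (n = 3) for each measured member of the 18 lists called by camera and of 6 further lists, with the number of measured members in brackets. Points are genes (red rose, blue fell, grey not past the threshold) and black lines are list medians, from -2.89 for ATP synthase to 1.57 for the Spx list.

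Over the 41 lists, camera with its preset correlation called 7 higher and 11 lower. With an estimated correlation 0 lists were called, the smallest adjusted p being 0.689, and fry called 1.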

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

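The 24 random-sequence control spots, which are not tested as genes, carried signal above the blank spots in replicate 3 in the red channel. Their median background-subtracted intensity was 129.5 on the unswapped array, where the 95th percentile of blank spots was 60.4, and 592.5 on the dye swap, where it was 401. The red channel held targocil RNA on the first and untreated RNA on the second, so the signal went with the channel and not with the treatment. On the other 4 arrays the red-channel median of these spots lay between -7.5 and 21.5. These spots enter the background model and, with the blank spots, the control limit, which in this channel was 138 and 714.8 on the 2 arrays. No explanation was tested.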

How the results depend on the processing

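The deposited ratios, the filter on genes above the controls and the fits without a single dye-swap array were chosen after the data were seen. All of the 157 genes that were tested under an alternative kept their direction there, except with swaps not turned, where 91 of 157 did. For many settings this was fixed in advance. All 157 had the same sign in 3 replicates, so leaving a replicate out could not turn them. The blocked, trend and robust, one-sample and filter settings reuse the same mean ratios. Direction was open only with other corrections or normalizations, the deposited ratios, a single array left out or a dye orientation alone. The count past the threshold was less stable, and the cause was not tested unless stated. With limma, 0 genes passed (0 rising, 0 falling, 0 at least 2-fold) without background correction (908 at an unadjusted p under 0.05, smallest adjusted p 0.0591), with plain subtraction (820 and 0.130) and with the authors' deposited ratios (927 and 0.119). The deposited ratios were not centred, and the median of all genes in them was -0.32. Their directions are therefore against 0 and include that shift. The plain one-sample test also gave 0 (0 rising, 0 falling, 0 at least 2-fold; 550 unadjusted), with 2 residual degrees of freedom. Median centring gave 298 genes, 134 rising and 219 at least 2-fold. Scaling the arrays to one spread gave 614, with 270 rising, 344 falling and 304 at least 2-fold. Genes above the control spots on at least 4 arrays gave 305 of 2076 tested, with 112 rising, 193 falling and 236 at least 2-fold. The 6 arrays with the replicate block gave 745, with 330 rising, 415 falling and 335 at least 2-fold, and with a dye term added to the replicate block 551, 229, 322 and 321. With consensus correlations of 0.118 and 0.408, array and swap of the same RNA counted in part as separate. These p-values are therefore likely too small, and their error rate was not tested. With the replicate block 34 of 54 named genes not past the threshold passed it, and the calls of the pyrimidine and biofilm lists were lost; it changed no other call of a named gene or a called list. The unswapped arrays alone gave 307 genes, 142 rising and 273 at least 2-fold, against 133 in the dye swaps alone. The trend and robust fit gave 108 genes and 67 falling, and leaving out the replicate 2 dye swap gave 199 genes with 84 rising. Leaving out a replicate gave 0 to 503 genes, 0 to 208 rising, 0 to 295 falling and 0 to 212 at least 2-fold.

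With swaps not turned 4 genes passed, 0 rising, 4 falling and 3 at least 2-fold, 0 of them among the 157, and 3 lists were called; here array and swap cancel by construction. Among named genes past the threshold those that turned were yceE -0.28, yceC -0.13, yceD -0.21, yceH -0.26, fabD 0.0314, fabHA 0.14, rplX 0.0049, rplJ 0.034, pbuX 0.34, sdhB 0.0793, cydB 0.17, yfiZ 0.35 and fhuC 0.0845, and among called lists the medians of the SigV and SigY regulons (-0.14) and of the motility (0.0928), pyrimidine (0.13), purine (0.0426) and TCA cycle (0.0188) lists; for the SigM regulon camera's direction turned, while the median of 5.83e-04 stayed above 0.

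Of 18 lists called, 14 to 18 stayed called in the settings that keep the preset correlation, apart from swaps not turned with 2; an estimated correlation left 0 and fry 1. The median of values in place of their mean could not be run with 2 spots per gene, nor the authors' value table, in which values below 0 are blank. Signal over background limits dim genes, such as pbuX, with -0.77 without background correction and -2.71 with plain subtraction. Of 54 named genes not past the threshold 23 moved by more than 1.5 times without replicate 1, 5 without replicate 2, 5 without replicate 3, 15 in the dye-swap arrays alone and 16 in the unswapped arrays alone. The medians of 11 of the 18 lists moved by more than 1.5 times with the deposited ratios, 9 with plain subtraction and 8 without replicate 1. With the deposited ratios they were -2.01 for Fur, -1.77 for respiration, -1.39 for glycerol, ribose, inositol and gluconate use, -1.11 for motility, -1.42 for purine, -0.69 for pyrimidine, 1.64 for CssRS and htpG, 0.57 for SigB, 0.54 for SOS and 1.21 for SigV and SigY, and the biofilm median also lay farther below 0. These ratios were not centred, so the shift of -0.32 over all genes is part of each of these medians.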

Other observations

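The tests below were chosen after the results were seen, except the count over sign choices.

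Beyond the fixed lists, 27 rising and 49 falling genes passed the threshold. The 27 include the yomS probe of the SPβ prophage, described below. Among the falling genes treP, the trehalose transporter, fell by 2.09 and treR, its repressor, by 2.08 beside treA, the mannose-6-phosphate isomerase gene manA fell by 1.65, and pdhA and pdhB, the E1 subunits of pyruvate dehydrogenase, fell by 1.76 and 1.89 (SD 0.37 and 0.45, n = 3). The gene infA fell by 1.38, adk by 1.14, secY by 1.43 and the elongation factor gene tsf by 0.99. The genes dctP and dctB, linked to dicarboxylate uptake, fell by 1.60 and 1.04, and lay above the control spots on 3 and 2 of 6 targocil arrays. Among the rising genes were yjbE at 1.65 and yjbF at 1.63, each above the control spots on 3 of 6 untreated arrays, aadK at 1.54 and ypmS at 1.79. The called genes ykvR, above the control spots on 0 of 6 untreated arrays, and yndH, above them on 0 of 6 targocil arrays, have only bounds near or under 1, so no fold is given.

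The 17 lists not reported above were not called, with camera adjusted p from 0.107 to 0.892. They were autolysins, lipoteichoic acid and D-alanylation, cell division, peptide antibiotic transporters, multidrug efflux, PhoPR, competence, early sporulation, cannibalism toxins, PBSX and SPβ prophages, anaerobic metabolism, overflow metabolism, and the lists for sulfur, branched-chain, tryptophan, and arginine and histidine metabolism. Single members past the threshold were xkdT of PBSX at 1.85, phoA of PhoPR at 0.88, pta of overflow metabolism, 2.01-fold lower, mdr of multidrug efflux at -1.73 (above the control spots on 3 targocil arrays) and spoVG of early sporulation at -1.10. In single alternatives 2 of the 17 were called higher: lipoteichoic acid and D-alanylation with median centring (adjusted p = 0.0386), without replicate 2 (adjusted p = 0.0396) and with the deposited ratios (adjusted p = 0.0151), and cell division with the deposited ratios (adjusted p = 0.0123). The autolysin list had a median of 0.07 (-0.10 without replicate 1 and 0.03 without replicate 2) and a mean of -0.22. For the early sporulation list the median was 0.02 and the mean -0.01.

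Turning the sign of a whole replicate leaves 4 choices of signs, too few for a share under 0.05; the real signs gave 157 genes and the highest of the others gave 0, so 1 of 4 choices gave as many.

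The lower ribosomal protein and ATP synthase genes may reflect the drug or the processing of bright probes. Intensity-dependent normalization as the whole cause is argued against by median centring, where the ribosomal median was -1.22 and the replicate medians -1.33, -1.11 and -1.08. Dye bias is argued against by the dye-swap arrays alone, with a ribosomal median of -1.12 against -1.20 in the unswapped arrays. With loess the replicate 1 ribosomal median was -0.79, so the normalization decided which replicate showed the smaller fall. A slower growth of treated cells and a direct response to the blocked exporter remain open and were not tested.

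Log2 ratios of replicate 1 spread wider, with an SD over genes of 0.91 against 0.47 and 0.55. The ratio of its spread to the mean of the others was 1.79 over all genes and 1.55 in the brightest 412 genes (bootstrap 95% interval over genes 1.47 to 1.64). Weak signal that affects only dim genes of replicates 2 and 3 would bring the ratio of bright genes to near 1, so it does not account for the whole difference. Added background that also narrows the ratios of bright genes is not excluded, since random-sequence spots carried signal in replicate 3. The interval treats genes as independent and takes in no variation between cultures. A stronger response in the culture of replicate 1 and a difference in labelling remain open.

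Probes for genes of the SPβ prophage, which PY79 is known to lack, offered a check on stray signal. Of 180 such probes 11, or 6.11%, lay above the control spots on at least 4 of 6 arrays in a condition, against 2065 of 3936 other probes (Fisher's exact p = 8.68e-40, two-sided), which argues against SPβ genes being transcribed like other genes; a silent prophage would also be dim, and 11 of 28 PBSX probes lay above the controls. Random noise of dim spots is argued against, since shuffling the probes within each array and channel gave at most 3 such probes, with a median of 0, in 10000 shuffles against 11. Among the 11, the yomS probe had 1.55 ± 0.24 (adjusted p = 0.0286, limma) and lay above the control spots on 1 of 6 untreated arrays. It is counted among the genes that rose, so the calls include a probe for a gene that PY79 is known to lack. The bdbB probe had 1.45 ± 0.72 (adjusted p = 0.0597, limma). Cross-hybridisation may play a part and was not tested, since probe sequences were not used here.

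Called genes lay side by side on the chromosome. Of 130 called genes that could be placed, 54 had a neighbour called in the same direction, against a median of 4 and a highest value of 21 in 10000 permutations, so calls scattered without regard to position are argued against. There were 8 runs of at least 3 such genes, holding 36 genes, among them yceC to yceH, treP to treR, mraY to spoVE, plsX to acpA and the 9 genes of ATP synthase. A candidate explanation is shared transcription in operons, which was not tested.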
